A study of Mus musculus with 4 samples.

How the data were processed

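Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on F9 cells, a mouse embryonal carcinoma line, with an antibody that the labels name K4me1 and that is read here as monomethylation of lysine 4 of histone H3 (H3K4me1), a mark of active and primed enhancers. The samples were 4 libraries: a ChIP and an input library of undifferentiated cells, and a ChIP and an input library of cells after 4 days of differentiation. Per the labels' protocols, differentiation was started with 1 µM retinoic acid in low-attachment dishes. Each state was thus represented by 1 ChIP library, with no replicates.

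Per the submitters' processing notes, the tools used were FastQC 0.11.3, Trim Galore, Bowtie2 2.3.3, SICER and ChIPseeker, with genome build GRCm38. Peaks were called with epic2, a version of the SICER method for broad marks, per the labels of the series' design; its version, bin size and gap setting are not given in the sources used here. The deposited lists hold the peaks of each ChIP library called against its own input, and nothing was pooled. Per the file headers, each peak has the read counts of the ChIP and of the input library, not scaled. The deposited p-value and FDR of each peak compare its ChIP count with its scaled input count, and every listed peak had an FDR under 0.05. The deposited log2 fold change of each peak was, from the values, the log2 of ChIP over input divided by 1 constant per library, which was 5.93 in the undifferentiated list and 3.69 in the day 4 list. An input count of 0 had been replaced by 0.25 reads, which affected 1994 undifferentiated and 6352 day 4 peaks. The deposited score was a multiple of that log2 fold and was not used further. Peak borders lay on a grid of 200 bp. Total reads per library are not given in the sources used here, so depth was known only inside peaks. ChIP reads in peaks came to 2616971 in the undifferentiated and 2985651 in the day 4 library, and input reads in the same peaks to 231091 and 331658. The authors' fold and FDR of a peak were used only to describe, rank or filter peaks within a list.

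Gene assignments and annotation classes (promoter, untranslated region, exon, intron, downstream, distal intergenic) were those the authors deposited for each peak, in the layout of ChIPseeker. Some gene symbols had been turned into calendar dates by a spreadsheet (33 undifferentiated peaks with 11 symbols and 53 day 4 peaks with 12 symbols), and all were restored through the gene identifiers of the RefSeq gene table for the same build. That table matched 99.9% of the undifferentiated and 99.95% of the day 4 peaks' identifiers. Gene coordinates came from that table and strand from the authors' annotation columns.

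From the lists, the number of peaks, the covered length and the widths were computed first. Overlap between the lists was found with bedtools 2.31.1 at a minimum of 1 bp, with Clopper-Pearson 95% intervals, and set beside the overlap left after shifting the peaks circularly along each chromosome (100 shifts). For each gene, the lengths of all peaks assigned to it were summed. For regions called in both lists with a reciprocal overlap of at least 50%, the ChIP count per kb was compared as log2 of day 4 over undifferentiated, centred on the median of all such regions because depth was unknown, with an exact interval from the counts. Intervals of ratios over sets of shared regions in the closing tests came from 2000 bootstrap draws of the regions. All other intervals cover counting error only. A sum of covered length moves with how much of the genome was called. ChIP reads per kb are therefore given beside the summed length for the pluripotency, retinoic acid response, Hox and endoderm lists. For the other lists and most single genes, covered length is given alone. The ranking of each list in covered length against random lists is relative to genes of similar covered length.

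Before the data were examined, 11 gene lists, the rule for named genes, the named regions and the alternatives were fixed. The lists covered pluripotency, retinoic acid response, Hox cluster, extraembryonic endoderm, neuroectoderm, mesoderm and primitive streak, trophoblast, fibroblast, housekeeping and enhancer histone modifier genes, and genes specific to blood, muscle, liver and pancreas. Some genes belong to more than 1 list. Named genes were Pou5f1, Sox2, Nanog, Klf4, Esrrb, Sall4, Lefty1 and Kdm1a in every case, the 5 genes with the greatest gain and the 5 with the greatest loss in covered length, the 3 members with the greatest absolute difference in each of the first 4 lists, and 1 such member of each other list. Some genes and regions that these rules select are not reported here. Members named beyond that rule were chosen after their values were seen, to spell out small counts or to serve as examples. With 1 library per state no test between conditions was made. Instead the median of each list was placed among 10000 random lists of the same size matched on decile of summed covered length or of mean density, as a description of these libraries; a list outside the 2.5th to 97.5th percentile is said to stand apart. This gave 11 lists for each of the 2 measures, and no correction was made for their number.

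The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data made from the 25382 undifferentiated peaks. In these data, 200 of 9332 genes were given a log2 density difference of 1.0. The median found for those genes was 1.01 and for the others -0.00057. The simulated peaks kept their borders and varied by counting error only, so this checks the arithmetic. It does not show how well density compares between lists whose borders differ. A difference in covered length was not simulated. The alternatives were a stricter FDR of at most 1e-10, a ChIP over input fold of at least 2, the day 4 list shortened to the number of undifferentiated peaks by FDR, merging of peaks within 3 kb, overlap of at least 50% of a peak's length, assignment of all peaks within 50 kb of a transcription start site (TSS), distal peaks only, a reciprocal overlap of 80%, and ChIP over input in place of ChIP density. Distal peaks in these alternatives are all peaks not annotated as promoter, so peaks within genes are included. Signal tracks were not used here.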

Results

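The study asked how enhancers keep pluripotency genes expressed in embryonal carcinoma cells, and the data compare H3K4me1 in F9 cells before and after 4 days of retinoic acid. There was 1 ChIP library per state, with no replicates, so every difference below describes these libraries and none was tested between conditions. A gene without a listed peak is a gene where the caller listed none, which does not show that the mark was absent. A gene with an assigned peak in 1 state alone can also have a peak at the same place that was assigned to a neighbouring gene in the other state.

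H3K4me1 was listed over more places at day 4, and most of those places were not listed in undifferentiated cells. The undifferentiated list held 25382 peaks over 142.5 Mb and the day 4 list 44237 peaks over 217.5 Mb, a ratio of 1.74 in number and 1.53 in covered length. Of the undifferentiated peaks, 12185 (48.0%, 95% interval 47.4 to 48.6%) were overlapped at day 4, against a mean of 16.8% (range 14.7 to 18.8%) after shifting. Of the day 4 peaks, 13042 (29.5%, 29.1 to 29.9%) were overlapped in undifferentiated cells, against 10.4% (9.10 to 11.8%) after shifting. This left 13197 peaks listed in undifferentiated cells alone and 31195 listed at day 4 alone, and the shared territory came to 52.4 Mb. Promoters, the regions next to gene starts, made up 30.4% (29.8 to 30.9%) of undifferentiated peaks and 22.3% (21.9 to 22.7%) of day 4 peaks, whereas distal intergenic regions made up 27.9% (27.3 to 28.4%) and 31.3% (30.9 to 31.8%). Peaks listed at day 4 alone were promoter peaks in 18.7% of cases and distal intergenic in 33.8%, while shared day 4 peaks were promoter peaks in 30.9%. The median peak was 4599 bp wide (quartiles 3399 and 6399 bp) in undifferentiated cells and 3799 bp (2799 and 5799 bp) at day 4. Over all covered length, the lists held 18.4 and 13.7 ChIP reads per kb. The authors' median log2 fold of ChIP over input was 1.05 and 1.5. With only peaks at an FDR of at most 1e-10, 30.2% of undifferentiated and 16.2% of day 4 peaks were overlapped, and the numbers of peaks were 11652 and 22964.

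Nearly every pluripotency gene with a listed H3K4me1 peak in undifferentiated cells also had one at day 4. Of 56 genes, 46 had an assigned peak in undifferentiated cells and 49 at day 4 (46 and 45 with equal peak numbers), and 44 had one in both. Rif1, a telomere-associated factor, had a peak in undifferentiated cells alone, and Nanog, Dppa4, Tdgf1, Lefty1 and Utf1 had one at day 4 alone. Among all 21887 protein-coding genes, by comparison, 9840 (44.96%) had a peak in undifferentiated cells, 12051 (55.1%) at day 4 and 7738 in both. The summed length over the pluripotency list was 1722 kb at 22.6 ChIP reads per kb in undifferentiated cells and 2189 kb at 16.8 reads per kb at day 4.

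Individual pluripotency genes differed in both directions. Esrrb, an orphan nuclear receptor of the naive pluripotency network, was covered over 100.6 kb in undifferentiated cells and 173.0 kb at day 4. Its broad peak over the 3' part of the gene was present in both states, at chromosome 12, 86452001 to 86530399, with 35.8 ChIP reads per kb and at 86440001 to 86514999 with 35.7 reads per kb (GRCm38). Input reads over the Esrrb peaks were also dense, at 3.58 and 2.74 per kb, where peaks on chromosome 12 had 2.08 and 2.18. The relative ChIP density at this shared region was higher at day 4 by a log2 of 0.36 (0.28 to 0.44). Sall4, a zinc finger factor of pluripotent cells, was covered over 23.0 and 81.6 kb, and Tcl1, a cofactor of Akt kinase, over 8.60 and 67.2 kb. Klf4, a reprogramming factor, had 1 peak of 4.8 kb in undifferentiated cells and 7 peaks over 32.2 kb at day 4. Nanog, a homeobox factor of pluripotent cells, had none in undifferentiated cells and 5 peaks over 39.8 kb at day 4, including 1 across the gene itself at chromosome 6, 122692801 to 122718399. Peaks that the authors assigned to its neighbours Dppa3 and Slc2a3 flanked Nanog in undifferentiated cells. The day 4 Nanog peaks had a low fold over input, 1.67 together and 1.47 for the peak across the gene. Their input was dense, at 3.07 reads per kb. In the 5 Mb of chromosome 6 from 120 Mb, input per kb at shared regions was 1.39 times the median bin in undifferentiated cells and 1.18 times at day 4. Whether this kept a Nanog peak off the undifferentiated list was not tested. Lefty1, a Nodal antagonist, had 2 peaks over 21.8 kb at day 4 alone.

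Sox2 and Pou5f1 (Oct4), the core pluripotency factors, showed shorter assigned length at day 4. Sox2 was covered over 32.4 kb by 4 peaks in undifferentiated cells and over 13.8 kb by 3 peaks at day 4, and the relative density of its 2 shared regions was lower by a log2 of -0.39 (-0.74 to -0.05). The ChIP over input fold of the peaks assigned to Sox2 went the other way, at 1.94 and 6.24, on 56 and 7 input reads. The undifferentiated peak at the Sox2 promoter (chromosome 3, 34641201 to 34650799) had no day 4 peak assigned to Sox2 in its place, although a day 4 peak assigned to Mir1897 reached into it. The Sox2 control region, an enhancer cluster 90 to 120 kb downstream, held 2 distal intergenic peaks in each state. Its main peak lay at 34753601 to 34766199 in undifferentiated cells, with 25.5 reads per kb and a fold over input of 2.46, and at 34753201 to 34765199 at day 4, with 19.0 reads per kb and a fold of 4.76. Pou5f1 was covered over 21.6 and 17.4 kb, with a ChIP over input fold of 1.09 and 2.73; its undifferentiated peak had a caller's FDR of 0.0375, close to the limit of the list. Within 10 kb of the Pou5f1 TSS there were 2 peaks in each state. The peak over the gene itself was assigned to its neighbour Tcf19 in both states. That peak was longer at day 4, at 11.6 kb in undifferentiated cells and 17.4 kb at day 4. It had 21.5 and 22.6 reads per kb and a fold over input of 1.40 and 2.27. The shorter assigned length of Pou5f1 thus leaves out the peak over the gene. The enhancer region 50 to 70 kb downstream of Klf4 held 1 peak over 5.20 kb in undifferentiated cells and 2 peaks over 13.8 kb at day 4.

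**Figure D1:**
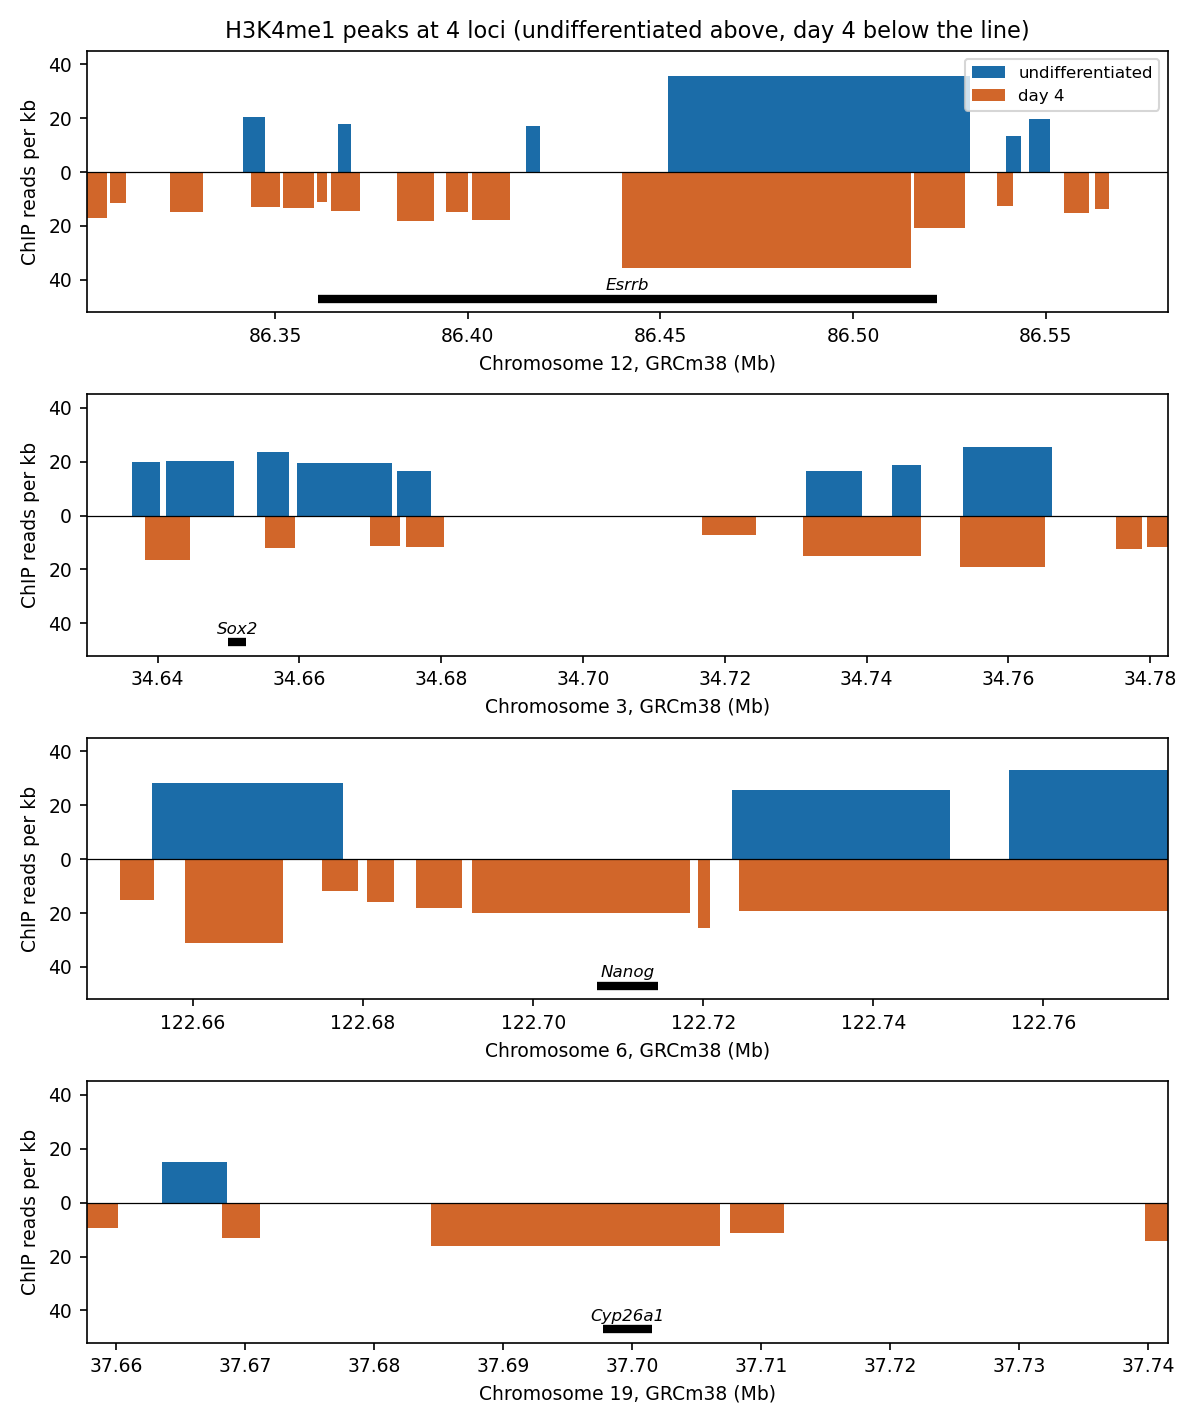
H3K4me1 peaks at Esrrb, Sox2, Nanog and Cyp26a1, with position on GRCm38 in Mb on the horizontal axis and mean ChIP reads per kb of each peak as height, undifferentiated cells above and day 4 below the line; black bars mark the genes. The broad Esrrb peak is present in both states at 35.8 and 35.7 reads per kb. Peaks spanning Nanog and Cyp26a1 are listed at day 4 alone, at folds over input of 1.47 and 1.32. Heights are not scaled between the libraries. The median region called in both lists has a day 4 over undifferentiated density ratio of 0.776, so a lower bar at day 4 is not in itself a loss.

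As a group, pluripotency genes did not stand apart from genes of similar covered length. The median difference per gene (day 4 minus undifferentiated) was 4.60 kb over 51 genes with a peak in either state, with 32 longer and 19 shorter, at the 8.4th percentile of random lists (median 9.998 kb). The median relative density at shared regions was -0.0074 on the log2 scale over 33 genes, at the 24.9th percentile; 7 of them were higher and 7 lower beyond counting error, among the higher Klf4 (0.72, interval 0.26 to 1.18) and Tbx3 (0.49, 0.25 to 0.73), and among the lower Klf5 (-0.39, -0.48 to -0.30) and Tfcp2l1 (-0.28, -0.44 to -0.13). Of all 3180 protein-coding genes with a shared region, 413 were higher and 348 lower beyond counting error. The rank of the pluripotency list in covered length turned with the peaks used. With peaks of at least 2-fold over input the median difference was 14.4 kb at the 99.5th percentile. With equal peak numbers it was -5.0 kb at the 4.9th.

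Retinoic acid response genes had listed peaks more often at day 4. Of 33 genes, 19 had a peak in undifferentiated cells and 29 at day 4 (19 and 27 with equal peak numbers), and 11 had one at day 4 alone, among them the receptor genes Rarb, Rxra and Rxrg and Cyp26a1, which encodes the enzyme that breaks down retinoic acid. Nr6a1, a nuclear receptor that represses pluripotency genes, was the exception, with a peak in undifferentiated cells alone. Rxra was covered over 0 and 53.0 kb, Nrip1, a nuclear receptor corepressor, over 0 and 39.99 kb, and Rara over 15.4 and 57.6 kb. At Cyp26a1, 2 peaks lay within 10 kb of the TSS at day 4 and none in undifferentiated cells; the longer one spanned the promoter (chromosome 19, 37684401 to 37706799; 360 ChIP reads, fold 1.32). No peak lay within 10 kb of the Rarb TSS in either state, with the TSS taken as the outer end of the gene. Start sites inside the gene were not examined, so this does not cover every Rarb promoter.

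The median difference for the retinoic acid list was 9.70 kb over 30 genes (26 longer, 4 shorter: Nr6a1, Nr2f1, Meis2 and Rdh10), at the 95.5th percentile of random lists. The summed length was 194.0 kb at 16.5 reads per kb and 570.5 kb at 13.8 reads per kb. Relative density at shared regions had a median log2 of 0.33, at the 98.9th percentile, but over 7 genes only, of which Tgm2, a transglutaminase induced by retinoic acid, was higher beyond counting error (0.69, 0.29 to 1.10). The covered length stood apart at an FDR of at most 1e-10 (98.0th percentile), with equal peak numbers (99.2nd) and with all peaks within 50 kb of a TSS (nearly every random list was lower). It did not with peaks of at least 2-fold over input (6.80 kb, 77.3rd percentile) or without promoter peaks (5.60 kb, 92.7th), and the density did not with equal peak numbers (0.25) or with ChIP over input (0.25).

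Few Hox genes, the homeobox genes of body axis patterning, had a peak assigned to them in both states. Of 39 genes, 11 had an assigned peak in undifferentiated cells and 18 at day 4, with 6 in both and 16 in neither. The difference depended on the assignment, since 23 Hox genes had a peak within 50 kb of the TSS in undifferentiated cells and 23 at day 4. Hoxb1, an early retinoic acid target, was covered over 3.80 and 28.8 kb, Hoxb3 over 0 and 18.8 kb and Hoxd10 over 0 and 8.20 kb. Hoxa11, Hoxb7, Hoxb9, Hoxc9 and Hoxd8 had an assigned peak in undifferentiated cells alone, but the Hoxb7 region was called in both lists and its relative density was higher at day 4 (log2 0.70, 0.22 to 1.18). The summed length was 55.2 kb at 16.3 reads per kb and 131.6 kb at 14.2 reads per kb, and the median difference was 2.0 kb over 23 genes, at the 42.0th percentile. With peaks at an FDR of at most 1e-10, 1 Hox gene had an assigned peak in undifferentiated cells and 10 at day 4, and with equal peak numbers the counts were 11 and 13.

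Extraembryonic endoderm genes, which mark the lineage that F9 cells form under retinoic acid, had longer covered length at day 4 than genes of similar coverage. Of 44 genes, 28 had a peak in undifferentiated cells and 38 at day 4, with 12 at day 4 alone; with equal peak numbers the counts were 28 and 32. These 12 included the endoderm transcription factor gene Sox17, the laminin chain gene Lamb1 and the parathyroid hormone receptor gene Pth1r. Amn and Fst had a peak in undifferentiated cells alone. The collagen IV gene Col4a2, a basement membrane component, was covered over 9.80 and 74.4 kb, and Gata4, an endoderm master regulator, over 12 and 49.99 kb. In the opposite direction Dab2, an endocytic adaptor of endoderm, was covered over 42.2 and 9.80 kb.

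The median difference for the endoderm list was 8.60 kb over 40 genes (32 longer, 7 shorter), at the 98.1st percentile of random lists (median 4.8 kb). The summed length was 304.9 kb at 17.4 reads per kb and 864.8 kb at 15.0 reads per kb. At shared regions, Sall4, Plat, Sparc, Gata6 and Nid1 had a higher relative density beyond counting error and none of the 14 genes a lower one. Sall4 is also in the pluripotency list and was counted as higher there too. The endoderm list had a median log2 of 0.14 at the 91.4th percentile. With ChIP over input this median turned to -0.13, at the 30.1st percentile. Of all 3180 protein-coding genes with a shared region, 413 had a higher and 348 a lower relative density beyond counting error. In covered length, the endoderm list no longer stood apart with peaks of at least 2-fold over input (9.0 kb, 90.2nd percentile). Nor did it without promoter peaks (6.40 kb, 89.3rd percentile).

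**Figure D2:**
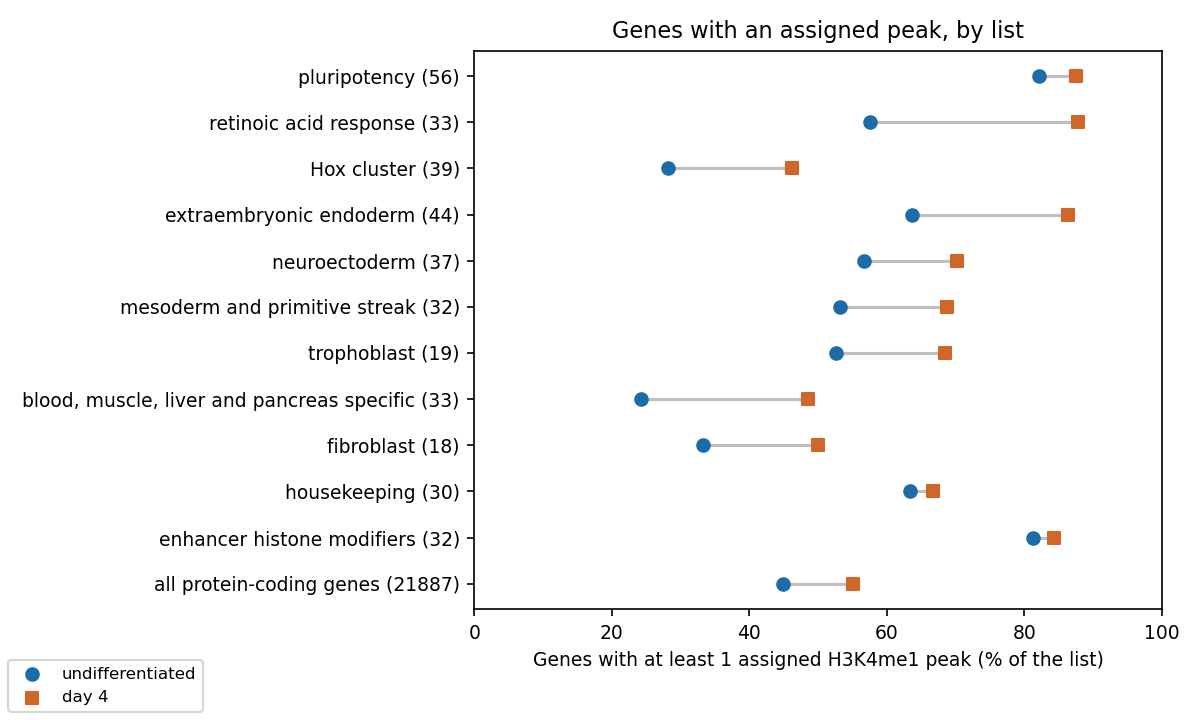
Share of the genes of each list with at least 1 assigned H3K4me1 peak, in percent on the horizontal axis, in undifferentiated cells (circles) and at day 4 (squares), with the number of genes in parentheses. Retinoic acid response genes lie at 57.6% and 87.9%, pluripotency genes at 82.1% and 87.5%, and all protein-coding genes at 44.96% and 55.1%.

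Genes of other lineages had a peak more often in the day 4 list, as protein-coding genes did in general, and with equal peak numbers little of this was left. The counts in undifferentiated cells and at day 4 were then 17 and 17 for mesoderm, 21 and 22 for neuroectoderm, 10 and 10 for trophoblast, 6 and 7 for fibroblast genes, and 8 and 10 for genes of blood, muscle, liver and pancreas. With all peaks, in the mesoderm and primitive streak list, 17 of 32 genes had a peak in undifferentiated cells and 22 at day 4; Gsc, an organiser homeobox gene, was covered over 30.6 and 96.4 kb. The median difference of 9.60 kb over 26 genes lay at the 99.6th percentile, at the 64.6th at an FDR of at most 1e-10 (4.20 kb) and at the 94.8th with equal peak numbers (3.0 kb). In the neuroectoderm list, 21 of 37 genes had a peak in undifferentiated cells and 26 at day 4, with a median difference of 4.20 kb at the 73.2nd percentile; Irx3, a homeobox gene, was covered over 44.8 and 203.4 kb. In the trophoblast list the numbers were 10 and 13 of 19, with 6.50 kb at the 75.9th percentile, and Fgfr2, a growth factor receptor gene, was covered over 17.0 and 104.8 kb. Genes specific to blood, muscle, liver and pancreas, which these cells should not use, had peaks in 8 and 16 of 33 cases (4.30 kb, 85.8th percentile), including Mb, the myoglobin gene, over 5.40 and 41.8 kb. Fibroblast genes had peaks in 6 and 9 of 18 cases (4.8 kb, 96.1st percentile), including Thy1 over 5.80 and 31.4 kb.

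Housekeeping genes and enhancer histone modifier genes had a peak about as often in both lists. With equal peak numbers the counts were 19 and 15, and 26 and 23. These day 4 counts stayed within 1.5 times those with all peaks. Of 30 housekeeping genes, 19 had a peak in undifferentiated cells and 20 at day 4, with a median difference of 1.80 kb at the 18.0th percentile; Gapdh, the glycolytic enzyme gene, was covered over 26.6 and 0 kb, although a day 4 peak assigned to another gene overlapped its undifferentiated peak. Of 32 genes of enzymes and partners that write or remove histone and DNA methylation or remodel enhancers, 26 and 27 had a peak, but covered length was shorter at day 4 for 16 of the 30 with a peak in either state. The median difference was -3.90 kb, at the 0.19th percentile, 5.40 kb at the 30.7th percentile with peaks of at least 2-fold over input, and 2.5 kb at the 1.12 percentile with all peaks within 50 kb of a TSS. Kdm1a (Lsd1), the demethylase of H3K4me1, was covered over 4.8 and 8.60 kb and the DNA methyltransferase gene Dnmt3a over 8.40 and 59.99 kb, while Suz12, a Polycomb subunit, was covered over 41.2 and 1.20 kb and Kmt2c, an H3K4 monomethyltransferase gene, over 45.4 and 2.80 kb. The mesoderm and modifier lists were taken up in the text because of these percentiles.

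**Figure D3:**
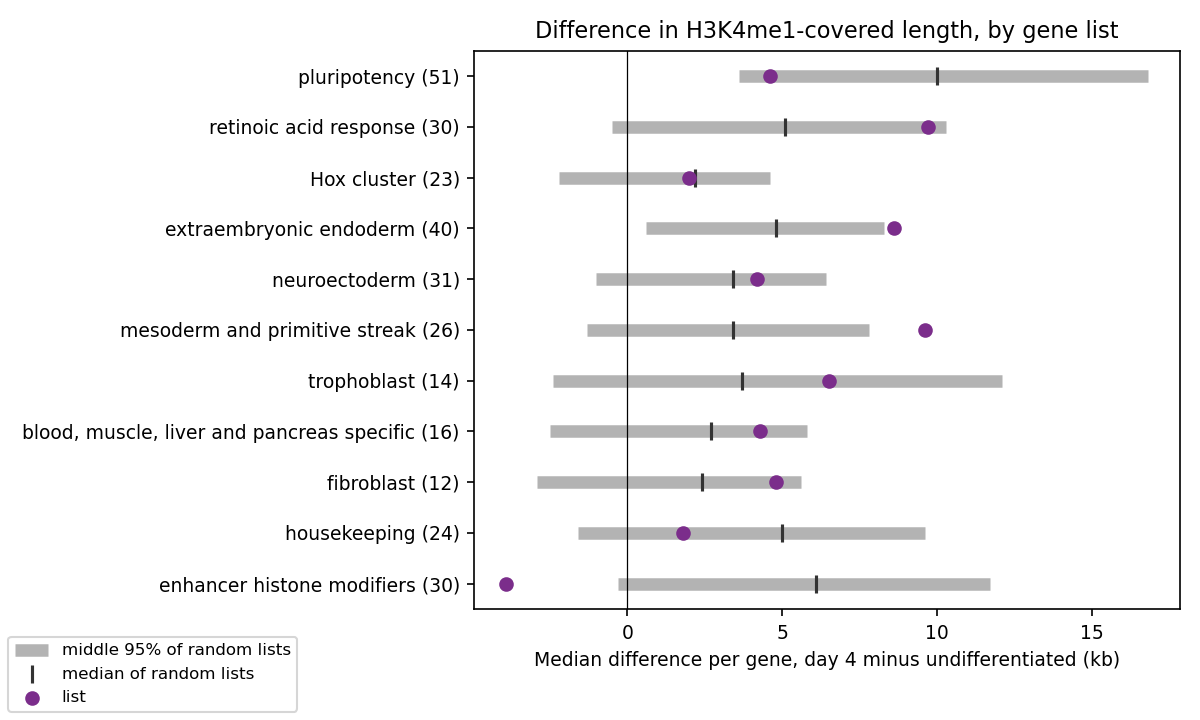
Median difference in H3K4me1-covered length per gene, day 4 minus undifferentiated, in kb on the horizontal axis, for each gene list (points; number of genes with a peak in parentheses), with the median (tick) and middle 95% (grey bar) of 10000 random lists of genes of similar covered length. The endoderm list at 8.60 kb and the mesoderm list at 9.60 kb lie above the bar and the histone modifier list at -3.90 kb below it.

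Over all genes, the differences in assigned length reached more than 150 kb in both directions. The 5 genes with the greatest excess at day 4 were Camta1, a calmodulin-binding transcription activator gene (35.2 and 227.8 kb), Cmip (25.4 and 203.0 kb), Vrk1, a nuclear kinase gene (84.8 and 260.4 kb), the noncoding gene 4933406K04Rik (77.4 and 246.6 kb) and Irx3 (above). In the 5 Mb of chromosome 12 from 105 Mb, which holds Vrk1, 4933406K04Rik and Tcl1, input per kb at shared regions was also higher at day 4, at 1.39 times the median bin against 1.13 times in undifferentiated cells. The 5 with the greatest excess in undifferentiated cells were the pseudogene 1700019M22Rik (265.6 and 2.0 kb), Flrt2, an adhesion protein gene (233.2 and 1.60 kb), Nrxn3, a neurexin gene (267.3 and 43.6 kb), Dach1, a transcription cofactor gene (215.0 and 12.2 kb), and Galc, a lysosomal enzyme gene (186.6 and 31.6 kb). Of these 5, all but Dach1 lie on chromosome 12. Around Flrt2, 1700019M22Rik and Galc (90 to 100 Mb), relative input density at 23 shared regions had a ratio of 0.933 (0.730 to 1.19) between day 4 and undifferentiated cells. At the 4783 regions called in both lists the centred log2 density differed between states with an SD of 0.37, where counting error alone gives 0.24.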

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

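All alternatives were chosen before the data were examined. Of 240 alternative values for 52 results, 161 were counted as unchanged and 79 were not. Counts, lengths and widths were counted as unchanged within 1.5 times the reported value, shares within their counting interval, and list medians where direction against random lists and side of the percentile limits stayed; the cause was not tested except where a setting by construction leaves fewer peaks. Depth limits single peaks in both lists: the median peak had 74 ChIP and 6 input reads in undifferentiated cells and 46 and 4 at day 4.

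At an FDR of at most 1e-10, the undifferentiated list held 11652 peaks over 67.3 Mb and the day 4 list 22964 over 122.9 Mb, and 30.2% and 16.2% of them were overlapped. At a fold of at least 2, the undifferentiated list held 13316 peaks over 60.8 Mb, the day 4 list covered 140.4 Mb, and 29.9% and 13.2% were overlapped. With equal peak numbers (25382), day 4 peaks covered 133.9 Mb, and 32.2% and 31.5% were overlapped; with overlap of at least 50% of a peak's length the shares were 33.9% and 20.4%, and with merging within 3 kb the day 4 share was 30.2%. Promoter shares were 28.8% (FDR) and 25.8% (fold) for undifferentiated cells and 21.5% (FDR), 19.5% (fold) and 21.5% (equal numbers) for day 4. Distal intergenic shares were 29.5% (fold) for undifferentiated cells and 30.8%, 31.9% and 30.9% for day 4.

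The number of genes with a peak in undifferentiated cells was 9 for retinoic acid response, 1 for Hox and 14 for endoderm genes at the stricter FDR, and 4 for Hox, 11 for mesoderm and 17 for histone modifier genes at a fold of at least 2. For Hox genes it was 23 within 50 kb of a TSS and 5 for distal peaks only, and at day 4 it was 10 at the stricter FDR, 23 within 50 kb of a TSS and 6 for distal peaks.

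For the median difference in covered length, direction turned, in sign or against random lists, in these cases where the list stood apart under either setting: pluripotency at a fold of at least 2 (14.4 kb), and histone modifiers at a fold of at least 2 (5.40 kb) and within 50 kb of a TSS (2.5 kb, at the 1.12 percentile of random lists). Among values that did not stand apart, pluripotency moved from below to above random lists at the stricter FDR (10.8 kb) and had a negative sign with equal peak numbers (-5.0 kb), as housekeeping did (-5.70 kb), while housekeeping moved above random lists at a fold of at least 2 (5.20 kb) and for distal peaks (4.8 kb). Retinoic acid response stood apart at the stricter FDR (7.0 kb), with equal peak numbers (5.0 kb) and within 50 kb of a TSS (18.0 kb). Hox genes moved from below to above random lists, at 3.40 kb (FDR), 2.60 kb (fold), 1.60 kb (equal numbers) and 12.2 kb (TSS window). Endoderm no longer stood apart at a fold of at least 2 (9.0 kb) or for distal peaks (6.40 kb), nor mesoderm at the stricter FDR (4.20 kb), at a fold of at least 2 (5.0 kb), with equal numbers (3.0 kb) or for distal peaks (5.0 kb).

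For relative density (log2), pluripotency moved to 0.12 with 80% reciprocal overlap. With ChIP over input the medians were 0.13 for pluripotency, -0.13 for endoderm, -0.20 for mesoderm and 0.095 for histone modifiers, and retinoic acid response no longer stood apart (0.25), nor did it with equal peak numbers (0.25). Histone modifiers stood apart for distal peaks only (-0.39, over 6 genes).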

Other observations

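The tests of library depth, of enrichment, of chromosome X copies and of copies of the chromosome 12 stretch were chosen only after the result was seen.

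Chromosome X differed from the autosomes. It held 596 peaks over 3.04 Mb in undifferentiated cells and 471 over 1.73 Mb at day 4, a ratio of 0.79, whereas the ratios of the autosomes ran from 1.35 on chromosome 12 to 2.28 on chromosome 19. The lower number lay in the distal part, 85 to 175 Mb, which held 550 and 365 peaks. The proximal part, 0 to 85 Mb, held more at day 4, with 46 and 106. On chromosome 12, the stretch from 90 to 100 Mb, which holds Flrt2, 1700019M22Rik and Galc, had 368 peaks over 2.17 Mb in undifferentiated cells, of which 239 were distal intergenic, and 161 peaks over 0.91 Mb at day 4, of which 41 were distal intergenic. The input of both states was dense elsewhere on this chromosome: in the 5 Mb from 85 Mb, which holds Esrrb, input per kb at shared regions was 2.04 times the median bin in undifferentiated cells and 2.0 times at day 4, from 100 Mb it was 1.56 and 1.59 times, from 105 Mb 1.13 and 1.39 times, and from 110 Mb 1.78 and 1.93 times.

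The larger number of peaks at day 4 was weighed against a deeper ChIP library and a stronger enrichment. Over the 4783 regions called in both lists, the background of the ChIP library, taken as input scaled by the caller's constant, was lower at day 4 by a ratio of 0.619 (0.607 to 0.631), which argues against greater depth. The fold of ChIP over scaled input was higher by a ratio of 1.29 (1.27 to 1.32), so a stronger enrichment in this immunoprecipitation may account for part of the additional peaks. A spread of the mark to new enhancers during differentiation stays open and was not tested, since state and library coincide.

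The lower number of chromosome X peaks at day 4 was weighed against a loss of X copies and against weak peaks. Relative to autosomes, input density at 50 shared X regions had a ratio of 1.01 (0.824 to 1.27) between day 4 and undifferentiated cells. The number of X peaks relative to other peaks had a ratio of 0.448 (0.396 to 0.506). A copy loss of that size over the whole chromosome is argued against. The regions were pooled over the chromosome, so a copy change of the distal part alone was not tested. At an FDR of at most 1e-10 the relative number of X peaks had a ratio of 0.421 (0.354 to 0.501). Weak peaks near the caller's limit thus do not account for the lower number of X peaks. What else differs between the states on chromosome X was not tested, and no biological explanation was tested.

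The chromosome 12 stretch, picked for its peaks, was weighed in the same way. Its number of peaks relative to the rest of the genome had a ratio of 0.248 (0.206 to 0.299) between day 4 and undifferentiated cells, and of 0.221 (0.161 to 0.304) at an FDR of at most 1e-10, which argues against weak peaks. Extra copies in the undifferentiated culture alone cannot be told apart from a chromatin difference: relative input density had a ratio of 0.933 with an interval of 0.730 to 1.19, because only 23 regions were shared. No biological explanation was tested, and state and culture coincide.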
